A study of Mus musculus with 19 samples.

How the data were processed

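Whole-genome bisulfite sequencing (WGBS), which reads methylated cytosines as C and unmethylated ones as T, was analysed in 4 libraries of mouse embryonic stem cells. The series holds 19 samples, and the other 15 (RNA-seq and ChIP-seq) were not analysed here. Per the labels' protocols, the cells had been adapted for 14 to 28 days to serum-free medium with LIF and a pair of inhibitors named 2i: PD0325901 at 1 µM, an inhibitor of MEK, and CH99021 at 3 µM, an inhibitor of GSK3. The growth protocol describes E14 cells only, and the days in 2i are given only as this range. Time in 2i may therefore have differed between the groups. Both replicates of the Eed knockout came from the J1 line (129S4/SvJae background) and both replicates of the Suz12 knockout from the E14 line (129/Ola background), per the labels. No wild-type WGBS library was analysed here, so knockout and cell line changed together. Samples were grouped by the titles GEO gives them. The labels do not say that replicates were separate cultures, so p-values cover at most the spread between these samples, which may be technical.

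The deposited files, 1 per library, list 21726070 CpGs each, with both strands of a CpG on 1 line, the coverage as a whole number of reads, and the methylated fraction. The authors gave the methylation as a fraction from 0 to 1, and its product with the deposited coverage was a whole number within 0.05 on all lines of all 4 files. Methylated reads were recovered as that whole number. The submitters' processing notes name the mouse build mm9, and the files list its unplaced sequences, so coordinates are given as in the files in mm9, counted from 1. STAR 2.5.2b and Bowtie2 2.0.2 are named in the submitters' processing notes without a role. The bisulfite aligner, duplicate removal and quality filters are not given in the sources used here. Duplicates that were kept, or reads of repeated sequence placed on 1 copy, would inflate coverage, and CpGs covered at over 10 times the median of their library were therefore left out in an alternative. No CpG was marked in the files as lost by mutation, so keeping or leaving out such sites made no difference.

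Coverage averaged 3.83, 5.65, 3.75 and 4.29 reads per CpG on chromosomes 1 to 19 and X in Eed replicates 1 and 2 and Suz12 replicates 1 and 2. These averages correspond to 81686018, 120419567, 80056951 and 91469346 reads over CpGs. A read over several CpGs counts at each of them, so counts within a region are not independent, and reads carry no molecular identifiers. Wilson 95% intervals and upper limits for a count of 0, set at 3 counts, therefore cover counting error only. At this depth single CpGs are measured coarsely, so reads were summed over regions.

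The level of a library was the methylated reads divided by all reads over all CpGs of chromosomes 1 to 19 and X. The same sum was taken per chromosome and per class of local density, defined as the number of listed CpGs within 250 bp either side of a CpG, itself included. Groups of 2 libraries were compared with an exact two-sided permutation test, for which the smallest p with 2 against 2 libraries is 0.333, so this test cannot make a call. Differences are given with the pooled SD of the replicates.

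Regions were 5 kb tiles with at least 10 CpGs, and CpG-dense regions, which are runs of CpGs with a local density of at least 25 that span at least 300 bp and hold at least 10 CpGs. At least 30 reads in each library were required. Summed methylated and unmethylated reads were compared with a quasi-binomial logistic model with group as the term. The Pearson dispersion, on 2 residual degrees of freedom, was moderated with squeezeVar of limma 3.58.1 in R 4.3.3 and kept at 1 or above. The prior degrees of freedom were 656 for tiles and 33.4 for CpG-dense regions. The replicate spread of a single region therefore had little weight. Very small p-values reflect mainly read counts and the dispersion shared across regions. An F test followed, or a chi-square test where the prior degrees of freedom were infinite, with Benjamini-Hochberg adjustment and a call at an adjusted p below 0.05. The groups, the tests, most settings to vary and the rule for named regions were fixed before the data were examined. In the moderation, a trend of the dispersion on the binomial information of a region was added after a first fit without it had been seen, because data simulated for the same regions gave too many false calls without it. It raised the calls from 179136 to 183091 tiles higher and from 6533 to 7250 lower in Eed, and lowered those of CpG-dense regions from 1102 to 1067 higher and from 315 to 285 lower. The minimum of 10 CpGs, fixed for tiles, was later applied to CpG-dense regions too.

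The model was tested on simulated data for each comparison, with 200 regions changed by 10 points and 200 by 20 points. Each region and library got independent noise with an SD of 0.1 on the logit scale. No shift was shared by all regions of a library. For 416839 tiles it recovered 7.0% and 54.0% of them, and 10 of 132 calls were false, which is 7.58%. Without the trend, 30 of 145 calls were false, which is 20.7%. For 16563 CpG-dense regions it recovered 88.5% and 99.5%, and 23 of 399 calls were false, or 5.76%, against 34 of 411 without the trend. No changed region was called in the wrong direction in these simulations. In the real data Suz12 replicates 1 and 2 differed genome-wide (30.0% and 32.4%), and 43.9% of tiles were called higher in Eed. The simulated rates of recovery and of false calls therefore need not hold for the reported calls. The simulated noise also makes the dispersion of a region grow with its binomial information, on which the trend was set. The fall in false calls with the trend was thus built into the simulation. It does not show that the trend suits the real data.

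The named regions are, of the tiles and of the CpG-dense regions, the 6 with the largest difference in each direction among called ones with at least 100 reads in each library and no CpG over 10 times the median coverage. Tiles methylated in every library were those at 50% or more in all 4 libraries, and tiles methylated in 1 group were at 50% or more in both of its libraries and under 25% in both of the other group. Alternatives changed the coverage minimum, the coverage limit, the size of regions, the density, a minimum difference of 10 points, the test (limma on log2 ratios of methylated to unmethylated reads with a pseudocount of 1), the centring, the depth, the replicates and the replicate block. Besides the trend and this minimum for CpG-dense regions, the fits without chromosomes 3, 6, 8, 14 and X, the bins of 1 Mb and 5 Mb, the stretches of chromosomes 6 and 14 and the thinned site levels were chosen after seeing the data. Centring shifted every region of a library alike on the logit scale.

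Promoters, gene lists and the targeted loci Eed and Suz12 had been planned. They need a gene annotation of mm9, which was not used here, and coordinates were not converted between builds. No gene is therefore named for a region, and the genotypes could not be checked at the targeted genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.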

Results

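DNA methylation was measured by WGBS in mouse embryonic stem cells that lacked either Eed or Suz12, both core subunits of Polycomb repressive complex 2 (PRC2), the enzyme complex that methylates lysine 27 of histone H3. The cells were grown in 2i medium, in which embryonic stem cells take on a ground state with low DNA methylation. There were 2 libraries of the Eed knockout (J1 line) and 2 of the Suz12 knockout (E14 line). Between 82.5% and 86.0% of the 21324789 CpGs on chromosomes 1 to 19 and X had at least 1 read in a library, and 33.3% to 51.5% had at least 5. Coverage averaged 3.83 and 5.65 reads per CpG in Eed replicates 1 and 2 and 3.75 and 4.29 in Suz12 replicates 1 and 2. The study's title concerns the crosstalk of PRC2 with other epigenetic layers in ground-state pluripotency. The comparison that these libraries allow is whether cells without Eed and cells without Suz12 carried the same DNA methylation. Each difference below is between knockouts that also differ in line and strain.

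CpG methylation was higher in the Eed knockout than in the Suz12 knockout. It was 40.5% ± 0.145 (SD, n = 2) in Eed and 31.2% ± 1.73 (SD, n = 2) in Suz12, a difference of 9.27 points against a pooled replicate SD of 1.23. Eed replicates 1 and 2 stood at 40.4% and 40.6%, and Suz12 replicates 1 and 2 at 30.0% and 32.4%. The Wilson 95% interval of Suz12 replicate 1, 29.9% to 30.0%, was far narrower than the gap to its replicate. Both Eed libraries lay above both Suz12 libraries, with an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries can give.

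At 189345 CpGs with at least 10 reads in all 4 libraries and at most 10 times the median coverage in each, all thinned to 10 reads, sites with 0 to 2 methylated reads made up 40.2% and 39.7% in the Eed libraries and 52.6% and 49.9% in the Suz12 libraries. Sites with 8 to 10 methylated reads made up 12.5% and 13.2% in Eed and 5.96% and 7.73% in Suz12. Sites with 3 to 7 methylated reads made up 47.2% and 47.1% in Eed and 41.4% and 42.4% in Suz12.

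The difference was larger at CpGs with up to 15 CpGs within 250 bp than at CpGs in denser sequence. CpGs with 4 to 7 CpGs within 250 bp were methylated at 47.0% ± 0.175 (SD, n = 2) in Eed and 35.4% ± 2.38 (SD, n = 2) in Suz12, a difference of 11.6 points. The class of 1 to 3 CpGs differed by 8.75 points (46.4% against 37.6%), and the class of 8 to 15 by 9.94 points (42.9% against 32.9%). In the class of 16 to 30 CpGs the levels were 29.3% and 25.3%, a difference of 3.97 points. CpGs with over 30 CpGs nearby, the density of CpG islands, were at 3.69% ± 0.146 in Eed and 3.47% ± 0.0951 in Suz12 (SD, n = 2), a difference of 0.221 points with a pooled SD of 0.123. In each of these classes both Eed libraries were above both Suz12 libraries, which chance gives with a share of 16.7% in a single class. The classes come from the same libraries and are not independent.

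**Figure D1:**
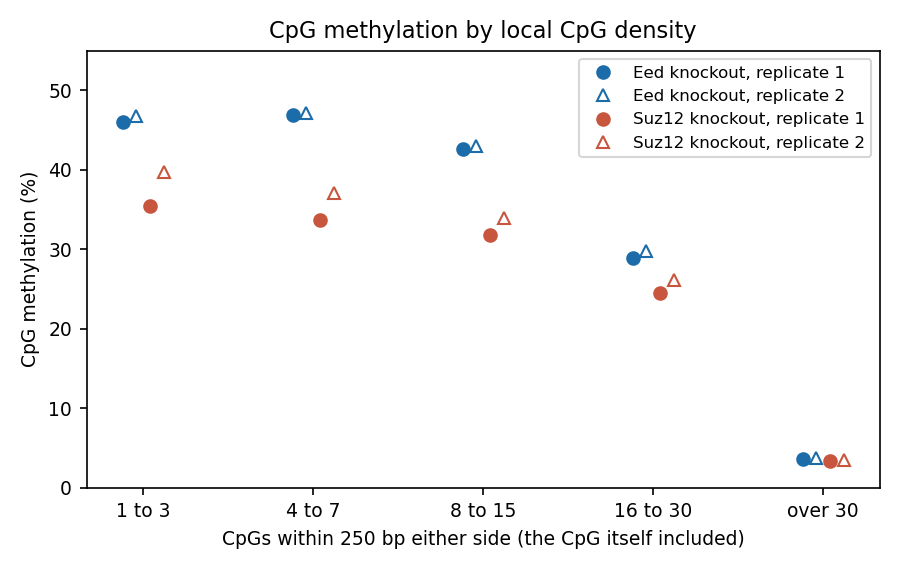
CpG methylation in percent (vertical axis) of each of the 4 libraries by the number of CpGs within 250 bp (horizontal axis), 1 symbol per library. The Eed libraries sit 11.6 points above the Suz12 libraries on average at 4 to 7 CpGs, and the group means are 3.69% and 3.47% at over 30 CpGs.

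Chromosomes 1 to 19 and X were each more methylated in both Eed libraries than in either Suz12 library. Chromosome 8 differed by 11.1 points (40.4% against 29.3%) and chromosome 11 by 10.8 points (36.4% against 25.6%). Chromosome 1 differed by 6.15 points, chromosome X by 6.48 points (42.5% ± 0.658 against 36.1% ± 2.34, SD, n = 2) and chromosome 2 by 6.67 points. At CpGs with at least 5 reads in all 4 libraries, the differences of chromosomes 1, 2 and X were 3.54, 2.20 and 3.35 points. Without CpGs over 10 times the median coverage, chromosomes 1 and 2 differed by 7.83 and 10.5 points. Chromosome Y went the other way, with 43.9% ± 1.90 in Eed and 54.4% ± 4.73 in Suz12 (SD, n = 2), a difference of -10.5 points with a pooled SD of 3.61.

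In bins of 1 Mb with at least 2000 reads in each library, both Eed libraries were above both Suz12 libraries in 2185 of 2561 bins (85.3%) and below both in 55. Unlike the levels by chromosome, these bins left out CpGs over 10 times the median coverage. The CpGs left out went the other way, at 45.2% in Eed and 51.1% in Suz12. For a single bin chance gives 16.7% each way. The bins share the library-wide levels, so they are not independent and their number does not act as replication. The median difference was 9.02 points, with quartiles of 5.44 and 11.1 points. Among these bins the largest excess in Eed lay on chromosome 17 from 6000001 to 7000000 of mm9 (41.1% against 23.8%). The largest excess in Suz12 lay on chromosome X from 31000001 to 32000000 (42.6% against 61.2%).

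Of 416839 tiles of 5 kb, 183091 (43.9%) were higher and 7250 (1.74%) lower in the Eed knockout under the quasi-binomial test with limma's moderation and Benjamini-Hochberg adjustment. The tiles called higher were at a median of 48.5% in Eed and 30.8% in Suz12. Tiles called lower were at a median of 42.6% in Eed and 62.0% in Suz12. Over all tiles tested the median difference was 9.70 points, with Eed higher in 85.0% of them. Of the called tiles 96.2% were higher in Eed. With each library centred on its own genome-wide level, 43119 tiles were higher and 27056 lower, so 61.4% of the called ones were higher. Leaving out Eed replicate 2 lowered the higher tiles to 103512. The lower tiles fell to 3667 without Eed replicate 1, to 3750 without Eed replicate 2 and to 4396 without Suz12 replicate 2.

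**Figure D2:**
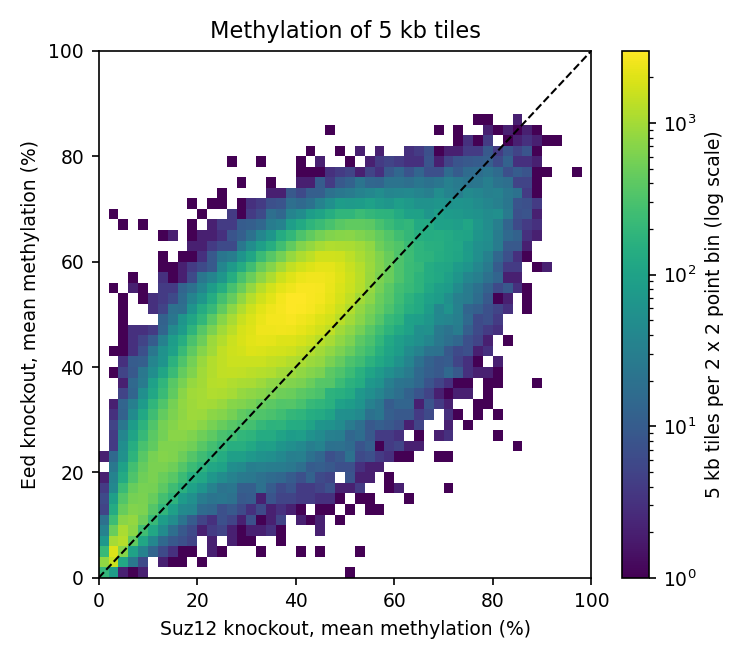
Mean methylation in percent of 416839 tiles of 5 kb in the Eed knockout (vertical axis) and the Suz12 knockout (horizontal axis), with colour for the number of tiles in each bin of 2 by 2 points on a log scale and a dashed line of equal levels. Eed was higher in 85.0% of the tiles.

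The tile with the largest excess in Eed lay on chromosome 3 from 145640001 to 145645000 (mm9), with 68.5% ± 1.06 in Eed and 3.42% ± 0.488 in Suz12 (SD, n = 2) over 64 CpGs and 292 to 709 reads per library (limma-moderated adjusted p = 3.9e-60). With limma on log2 ratios the adjusted p of this tile was 0.0020. A tile on chromosome 7 from 140230001 to 140235000 was at 66.4% ± 0.253 in Eed and 4.50% ± 0.682 in Suz12. Its neighbour from 140235001 to 140240000 was at 64.6% ± 1.57 and 13.5% ± 0.733, so this stretch of chromosome 7 was methylated in Eed cells and mostly unmethylated in Suz12 cells. Tiles on chromosome 18 from 57995001 to 58000000 (66.4% against 8.68%), on chromosome 1 from 123350001 to 123355000 (55.4% against 3.36%) and on chromosome 5 from 9150001 to 9155000 (65.6% against 15.7%) completed the set of 6.

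In the opposite direction, the tile on chromosome 15 from 97385001 to 97390000 was at 24.1% ± 1.83 in Eed and 84.3% ± 1.48 in Suz12 (SD, n = 2) over 150 CpGs and 167 to 411 reads per library (limma-moderated adjusted p = 6.4e-41). Chromosome 4 from 155510001 to 155515000 was at 30.6% in Eed and 80.9% in Suz12, and chromosome 9 from 91280001 to 91285000 at 22.4% and 70.5%. The tile on chromosome 8 from 116920001 to 116925000 was nearly unmethylated in Eed, at 0% of 101 reads, which allows up to 2.97%, and 2.80% of 143 reads, and at 52.3% and 47.8% in the Suz12 libraries. The remaining ones were chromosome 11 from 11925001 to 11930000 (16.6% against 58.4%) and chromosome 5 from 53290001 to 53295000 (36.5% ± 12.5 against 78.2% ± 2.42).

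CpG-dense regions were mostly unmethylated in both knockouts. Of 16563 such regions, 14406 (87.0%) were under 10% in every library. The test called 1067 (6.44%) higher and 285 (1.72%) lower in Eed. Regions called higher had medians of 21.8% in Eed and 5.40% in Suz12, and those called lower 52.0% and 74.0%. Of these calls 78.9% were higher in Eed. With each library centred on its genome-wide level, a shift applied alike to every region whatever its own difference, 560 regions were higher and 880 lower, or 38.9% higher among the called ones. With limma on log2 ratios 189 regions were higher and 21 lower. Without Suz12 replicate 2 there were 657 higher and 116 lower regions.

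The CpG-dense region with the largest excess in Eed lay on chromosome 9 from 21992461 to 21993008 (mm9), with 63.9% ± 0.0669 in Eed and 4.87% ± 0.601 in Suz12 (SD, n = 2) over 42 CpGs and 135 to 527 reads per library (limma-moderated adjusted p = 6.4e-11). Chromosome 7 from 25370611 to 25371139 was at 67.1% against 11.7%, and chromosome 19 from 10500780 to 10501085 at 79.1% against 25.8%. Chromosome 10 from 42351861 to 42352418 was at 58.0% against 6.18%, chromosome 19 from 30613867 to 30614417 at 59.0% against 8.17%, and chromosome 9 from 66653560 to 66654032 at 56.3% ± 14.6 against 7.47% ± 2.65.

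Among CpG-dense regions higher in Suz12, the largest difference was on chromosome 5 from 53292918 to 53293944, within the tile named above, at 33.4% ± 10.0 in Eed and 83.2% ± 2.22 in Suz12 (SD, n = 2). Regions on chromosome 4 from 155511081 to 155512409 (39.0% against 85.7%) and on chromosome 11 from 11925414 to 11926786 (13.5% against 58.1%) also lay within named tiles. Chromosome 13 from 85608682 to 85610044 was at 39.1% against 81.0%. Chromosome 12 from 105685226 to 105685553 was at 16.6% ± 2.08 against 53.9% ± 0.569, and chromosome 18 from 13131626 to 13132998 at 17.0% ± 1.94 against 53.1% ± 3.62. All 24 named regions were called in the same direction in all 310 combinations of a region and an alternative that were fitted. The highest adjusted p was 0.040, with limma on log2 ratios. The named regions had been picked as the largest called differences, and the alternatives refitted all or part of the same reads. The rule of selection already met the alternative limits of coverage. This agreement was therefore largely fixed by the selection and is not independent support. The named tiles on chromosomes 3 and 8 had no fit without these chromosomes.

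**Figure D3:**
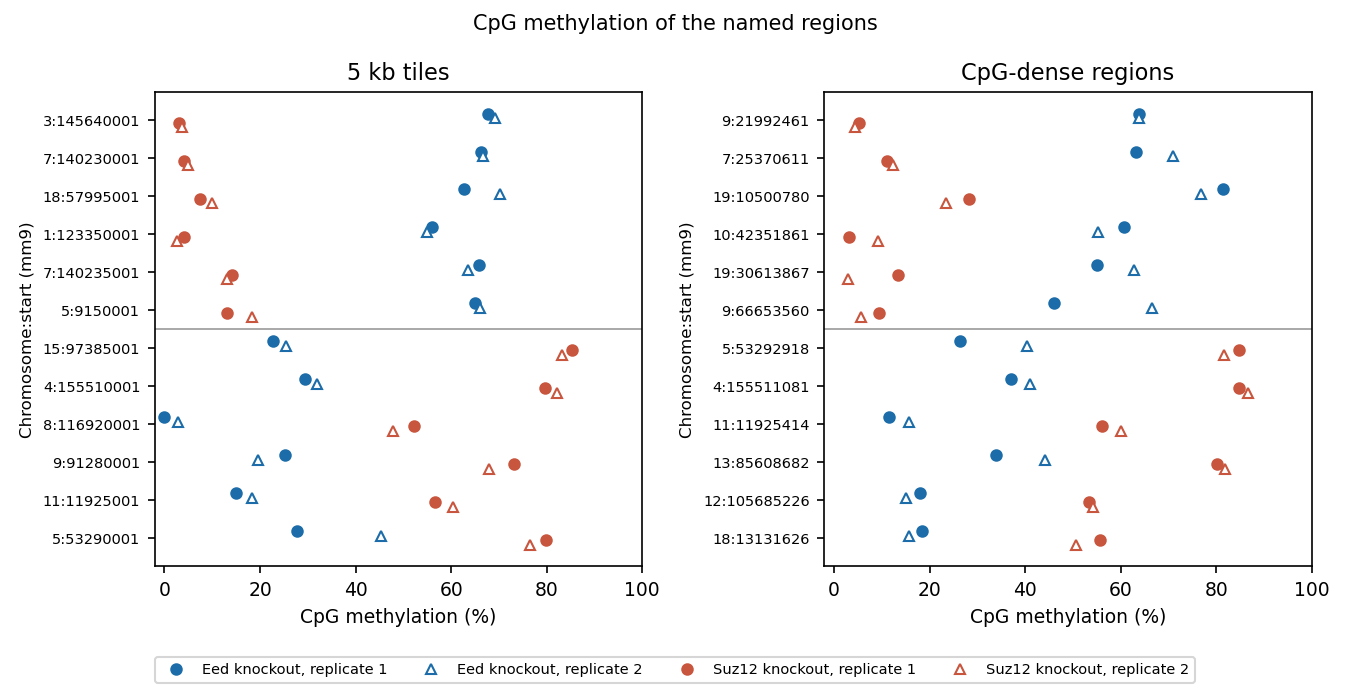
CpG methylation in percent (horizontal axis) of the named 5 kb tiles (left) and CpG-dense regions (right) in each of the 4 libraries, with the regions higher in the Eed knockout above the grey line and those lower below it. In each region both libraries of a group lie on the same side of both libraries of the other.

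Methylation was at 50% or more in every library at 28806 tiles (6.91%), and at 57234 tiles without Suz12 replicate 1. At 70% or more in every library there were 540 tiles. Tiles at 50% or more in both Eed libraries and under 25% in both Suz12 libraries numbered 391, and 24 tiles showed the converse. Leaving out any 1 of the 4 libraries raised these numbers, to between 918 and 2193 and to between 45 and 129. Fewer libraries must then pass, so counts of this kind can only stay or rise when a library is left out. At 70% or more in 1 line and under 25% in the other, there were 0 tiles in either direction. Among CpG-dense regions 597 were at 50% or more and 149 at 70% or more in every library.

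Read depth differed between the knockouts over long stretches of chromosomes 3, 6, 8 and 14. Relative to the median autosome, the depth of the Eed libraries over that of the Suz12 libraries was 1.44 on chromosome 3, 1.40 on chromosome 8 and 1.45 on chromosome 6 from 20000001 to its end. It was 0.528 on chromosome 14 from 95000001 to its end. It was between 0.971 and 1.02 on the 15 other autosomes, 0.970 on the first 20 Mb of chromosome 6 and 0.991 on the first 90 Mb of chromosome 14. In 5 Mb bins of the 15 other autosomes, the log2 ratio ranged from -0.38, on chromosome 1 from 120000001 to 125000000, to 0.21. Outside chromosomes 3, 6, 8, 14 and X, methylation differed by 9.10 points, with a pooled replicate SD of 1.18.

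**Figure D4:**
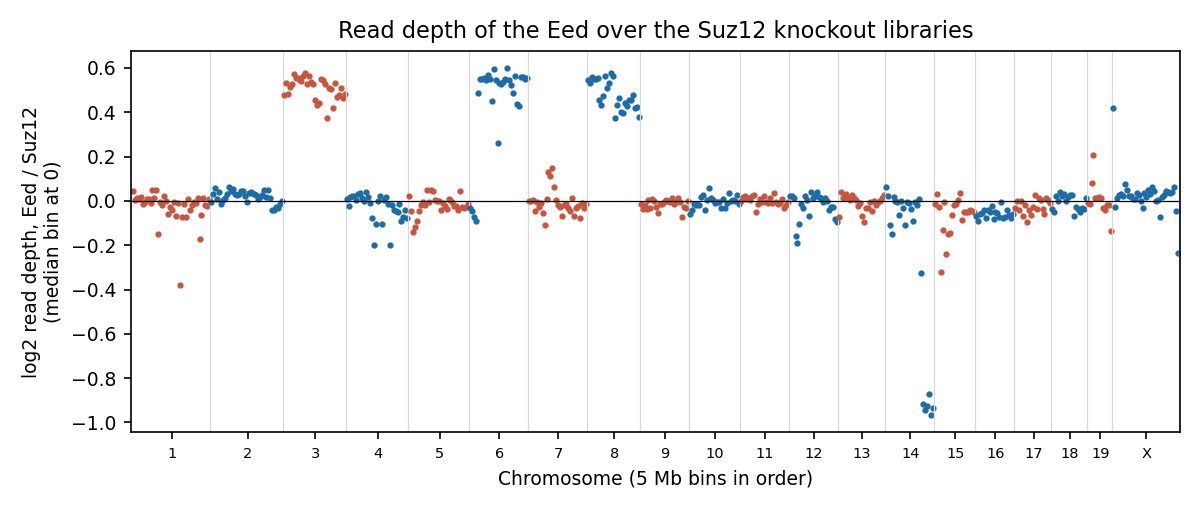
Read depth of the Eed over the Suz12 knockout libraries (vertical axis, log2, with the median bin at 0) in 5 Mb bins along chromosomes 1 to 19 and X (horizontal axis, colours alternate by chromosome). Bins of chromosomes 3 and 8 and of chromosome 6 beyond 20 Mb lie at a median of 0.53, and the last 6 bins of chromosome 14 at a median of -0.93.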

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

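The tests of explanations in this part were all chosen after the results were seen. Signals outside the main measurement came from CpGs of chromosome M, of a lambda sequence and of unplaced sequence. CpGs of chromosome M were methylated at 14.9% and 3.54% in Eed replicates 1 and 2 and at 25.6% and 22.1% in Suz12 replicates 1 and 2, over 57508 to 70154 reads. Chromosome M had been planned as the background of incomplete conversion. The lambda sequence had 4, 10, 7 and 19 reads in Eed replicates 1 and 2 and Suz12 replicates 1 and 2. In Suz12 replicate 1, 4 of the 7 were methylated, or 57.1% with a Wilson 95% interval of 25.0% to 84.2%. In Eed replicates 1 and 2 and Suz12 replicate 2 it was 0 of 4 (interval up to 49.0%), 1 of 10 (10.0%) and 3 of 19 (15.8%), too few reads in each library for a conversion rate.

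Sequence assigned to chromosome Y but not placed on it was methylated at 41.6% in Eed and 54.3% in Suz12, and other unplaced sequence at 39.2% and 50.0%, although its CpGs with over 30 CpGs nearby went the other way, with 25.2% ± 1.65 in Eed and 21.6% ± 0.434 in Suz12 (SD, n = 2). Chromosome Y itself went the same way, and so did the 32623 CpGs of chromosomes 1 to 19 and X at over 10 times the median coverage, with 45.2% ± 0.995 in Eed and 51.1% ± 0.163 in Suz12 (SD, n = 2), against the genome-wide excess in Eed. Incomplete bisulfite conversion in the Suz12 libraries would have raised CpGs with over 30 CpGs nearby by about as many points as chromosome Y, and these were at 3.47% in Suz12. Chromosome M, the planned background, was higher in Suz12, which taken alone goes with poorer conversion there. The measures disagree, and a background as high as on chromosome M did not hold for the nuclear CpGs of that class. Very deeply covered CpGs were not the whole cause on the other unplaced sequence, where the difference went from -10.8 to -8.00 points without them. On chromosome Y only 1 of 17703 CpGs was so covered, and leaving it out tested nothing there. How reads of repeated copies were placed was not tested, and genotype and cell line stay open.

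The genome-wide excess of methylation in Eed was weighed against 3 explanations. Incomplete bisulfite conversion would have shown most at CpGs with low methylation, and the CpGs with over 30 CpGs nearby differed by 0.221 points. Chromosome M, the planned background, was higher in Suz12, opposite to this excess. Sequencing depth is argued against by the pair of most similar depth, Eed replicate 1 and Suz12 replicate 1, which differed by 2.03% in depth and by 10.4 points in methylation. Eed replicate 2 had 47.4% more reads per CpG than Eed replicate 1, with levels 0.205 points apart. Cell line and strain cannot be told apart from the knockout, because each genotype was measured in 1 cell line.

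For the depth excess of the Eed libraries on chromosomes 3, 6 and 8 and the deficit on distal chromosome 14, uneven coverage by CpG density is argued against, since the ratio within classes of equal density was lowest at 1.40 on the 3 gained chromosomes. Local repeats would have raised a few bins. The lowest of the 85 gained bins of 5 Mb was at 0.26 on the log2 scale. The 386 bins on the 15 other autosomes ranged from -0.38 to 0.21. The gained stretches were chosen after the depth was seen, without the start of chromosome 6, so this gap is partly built in. Chromosomes 3 and 8 were taken whole, and none of their bins lay below 0.26, which a few raised bins would not give. Extra and missing chromosome copies in the Eed knockout line are a candidate explanation, as a hypothesis: the gained bins had a median fold of 1.44 and the 6 lost bins of 0.525, and libraries of 1 line differed by at most 0.09 on the log2 scale in the gained bins. Relative to the median autosome of the same line, chromosomes 3, 6 and 8 were at 1.20, 1.30 and 1.44 in Eed, its 3 highest autosomes, and at 0.848, 0.935 and 1.05 in Suz12. Chromosome 14 was at 0.383 in Eed and 0.738 in Suz12 beyond 95 Mb, against 0.875 and 0.898 on its first 90 Mb, values that go with a change in Eed and leave one in Suz12 open.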

How the results depend on the processing

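The dispersion trend, and the alternatives without chromosomes 3, 6, 8, 14 and X, were chosen after seeing the data. The genome-wide difference stayed within its replicate SD under 9 alternatives. Among the 9, leaving out 1 library could not move the difference beyond this SD, by arithmetic with groups of 2. The replicate block returned the same value by construction. Only the other alternatives could have moved it further. For site levels at CpGs with at least 10 reads in all 4 libraries, without an upper coverage limit, the difference was 6.93 points (220657 CpGs). No direction turned among the differences by density and by chromosome. At CpGs with at least 5 reads they moved by more than their SD on chromosomes 1, 2 and X, to 3.54, 2.20 and 3.35 points. Without CpGs over 10 times the median coverage and with no minimum of reads, chromosomes 1 and 2 differed by 7.83 and 10.5 points. The low values there thus depended in part on very deeply covered CpGs. Both limits were not applied together, and chromosome X was not checked in this way. Tiles higher in Eed stayed within 1.5 times the reported count in 13 of 16 alternatives. The exceptions were 43119 after centring, 70893 with 20 kb tiles, of which fewer exist, and 1 omitted library, Eed replicate 2. As a share of the tiles tested, the 20 kb tiles were at 56.3%, against 43.9% in the reported fit. Tiles lower in Eed numbered 3595 at a minimum of 100 reads (1.53% of those tested), 27056 after centring and 3283 with 20 kb tiles (2.61%). The share in the reported fit was 1.74%. CpG-dense regions higher in Eed numbered 667 with a minimum difference of 10 points, 189 with limma on log2 ratios, 560 after centring and 417 at a density of at least 30. Those lower numbered 177 at a minimum of 100 reads, 21 with limma, 880 after centring and 74 at a density of at least 30. Tiles methylated in every library numbered 540 at 70%, and by their definition could only stay or rise in number when a library was left out. Beyond smaller sets of regions and stricter limits, the cause was not tested. Leaving out 1 library in turn, with the lone library assumed to vary like the other group, gave 103512 to 182729 tiles higher and 3667 to 8565 lower, 657 to 1140 CpG-dense regions higher and 116 to 238 lower, and 31098 to 57234 tiles methylated in every library. Replicates of the same number did not deviate together (correlation of 0.022 over tiles and 0.089 over CpG-dense regions), and the labels name no shared day. With the replicate block 184108 tiles were higher and 7841 lower, and 1071 and 309 CpG-dense regions, each within 1.5 times the reported count. Promoters, gene lists and targeted loci were not run, for want of an annotation of the build used here. Tiles called higher had a median of 232 reads per library and those called lower 119, against 148 over all tiles tested.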

Other observations

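The sets in this part were chosen after their values were seen. CpG-dense regions at intermediate methylation, from 40% to 60% in both libraries of a line, were counted by whether the other line was under 25% in both libraries. Of 313 regions at an intermediate level in Eed, 61 were low in Suz12, and of 95 at an intermediate level in Suz12, 5 were low in Eed. In mm9 the 5 lay on chromosome 7 from 30577771 to 30578370, chromosome 12 from 105685226 to 105685553, chromosome 13 from 120276738 to 120277915 and chromosome 18 from 13131626 to 13132998 and from 30429013 to 30429367. The region on chromosome 13 was at 5.10% and 8.37% in the Eed libraries and at 52.2% and 54.1% in the Suz12 libraries. It was called lower in Eed, with at least 392 reads in each library, and differed by more than some of the named regions. It is not among them, so by their rule it must hold a CpG above the coverage limit. Whether misplaced reads of repeated sequence contributed to its levels was not tested. Regions at 40% to 60% in all 4 libraries numbered 41.

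Tiles lower in Eed more often held a CpG at over 10 times the median coverage than all tiles tested, 825 of 7250 (11.4%) against 1.15%, and 6425 of the lower tiles held none. The lower tiles also had less depth in Eed. Their median log2 ratio of Eed over Suz12 depth, scaled to library totals, was -0.165. It was -0.0135 in tiles called higher and -0.0193 over all tiles tested. On chromosome X, 2980 of 10688 tiles were higher and 350 lower in Eed.

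Runs of at least 5 CpGs without a read in both libraries of 1 line, and with at least 3 reads in both of the other, numbered 559 for Eed and 39 for Suz12. The longest run without reads in Eed held 45 CpGs on chromosome 12 from 115616560 to 115617449, where the Suz12 libraries had 5.18 and 6.18 reads per CpG. The longest without reads in Suz12 held 12 CpGs on chromosome 7 from 104937633 to 104937731, where the Eed libraries had 5.42 and 5.50 reads per CpG. The genes at these positions were not assigned here.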
